A study of Mus musculus with 48 samples.

How the data were processed

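Poly(A)-selected RNA of mouse bone and MLO-Y4 cells was sequenced, per the labels' protocols. The authors deposited 4 tables of FPKM values (fragments per kilobase of transcript, scaled to the sequenced fragments of each library), each with 55335 gene rows. The tool that made them is not given in the sources used here; the submitters' processing notes name HTSeq and mm10, with no role. Groups were taken from sample titles, and 27 libraries in 9 groups had values here; 21 of 48 samples and 7 of 16 groups were not analysed here, so the planned knockdown comparison was not made. Tests were made only within a table. Some labels are in doubt. The treatment label of vehicle samples names oligomycin A with DMSO, while title and protocol say vehicle. It also gives 50 mM, which the protocol gives as the stock, with a working concentration of 50 µM. The protocol of the old cortical bone says that nonosseous tissue with marrow was harvested.

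FPKM are not counts. For genes with 1 transcript in GENCODE M21 (GRCm38, the assembly that mm10 names), low values times length clustered at steps, which gave an approximate depth. Only 21.7% to 38.5% of low values were whole within 0.1 of a fragment, so counts were not recovered and no count test was run, although the design had allowed for counts. This share was 33.5% to 38.5% in MLO-Y4 libraries, 22.3% to 23.3% in old bone and 21.7% to 29.1% in young bone. Evenly spread values would give a share not far below those of bone, so the bone depths are rough. Of the gene IDs 55154 were found in GENCODE M21, which gave positions. No 2 libraries of a table shared more than 0.0256% of their values.

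Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a trended variance prior, on genes with a mean FPKM of at least 1 over the libraries of the fit. Fold changes are on this scale, which understates the change of low genes. The 4 oligomycin A groups shared 1 fit. Benjamini-Hochberg adjusted p below 0.05 was the threshold. The 39 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were measured. Named genes followed a rule fixed before the data were examined. With at least 20 calls, these were the 8 largest changes in each direction among called genes with non-overlapping libraries, a mean of at least 5 FPKM in the higher group and no predicted name, then up to 4 members of each list that passed, by p. With fewer, they were all called genes with a name and the 5 next by p. A fixed set of purinergic, osteocyte and stress genes was added. Some genes that the rule named are not reported here.

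Simulated data with 200 genes changed by 1 on the log2 scale were used to test the fits. Of these, 95.5% were recovered in the simulation of treated cells (11902 genes), 98.0% in that of recipients, 87.0% in that of their difference, 95.5% in that of the vehicle pair (11902 genes each), 97.0% in that of ADP (11604 genes) and 0% in that of bone medium transfer (16438 genes). Noise was drawn independently for each gene and library. Of the called genes, 60 of 636 in treated cells and 7 of 46 in recipients changed by at least 1, so recovery of smaller changes was not tested. Other pseudocounts, filters, scalings, variance priors and replicate blocks and the omission of single libraries were tried as alternatives.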

Results

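RNA sequencing was carried out on mouse bone and on MLO-Y4 cells, a mouse cell line with features of osteocytes, the cells embedded in bone matrix. FPKM values of 27 libraries in 9 groups of 3 were used. The other 21 of the 48 samples, which include 1 µM ADP and the receptor knockdown cells, were not analysed here. Estimated depth was 14.9 to 25.3 M fragments in the MLO-Y4 libraries, 31.1 to 35.4 M in old cortical bone and 1.62 to 6.85 M in young bone fragments. The bone estimates are rough, since low values clustered only weakly at steps there. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

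Oligomycin A, an inhibitor of mitochondrial ATP synthase, was given to MLO-Y4 cells for 1 h, and the comparison with vehicle asks what blocking ATP synthase does to the cells' transcripts. Immediate early genes, which respond to stimuli without new protein synthesis, rose: 20 of 28 measured members were higher and 0 lower, and 25 were higher when adjusted over the list alone. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand, GRCm38, protein-coding), a subunit of the AP-1 transcription factor, went from 31.9 ± 2.17 to 435 ± 19.98 FPKM (SD, n = 3 each), a log2 fold change of 3.73 ± 0.13 (SE). Ier2 rose by 3.20, Zfp36, which promotes mRNA decay, by 2.84, Arc by 2.48, Btg2 by 2.44 and Egr1, a zinc finger transcription factor, by 2.25 on the log2 scale. Ddit3 (chromosome 10, 127290774 to 127296288), the stress transcription factor CHOP, went from 48.6 ± 2.15 to 418 ± 8.93 FPKM, and Chac1, a glutathione-degrading enzyme, from 40.1 ± 7.84 to 195 ± 7.39 FPKM (SD, n = 3 each).

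Of 21 measured integrated stress response genes, 10 were higher and 0 lower in treated cells, among them Ddit4 at a log2 fold change of 1.63 and Sesn2 at 0.89. Adjusted over the list alone, 12 were higher. Of 19 NF-kB and cytokine genes 7 were higher and 0 lower, with Ptgs2, the inducible cyclooxygenase, at 1.09, Nfkbia at 1.11, Nfkbiz at 0.93 and Il6 at 0.82. Among 14 heat shock chaperones 3 were higher (Dnajb1 at 1.18, Dnaja1 at 0.44 and Hsp90aa1 at 0.31), and among 17 hypoxia response genes 3 were higher (Bhlhe40 at 0.73, Vegfa at 0.38 and Rora at 0.33). By camera the adjusted p was 2.71e-38 for immediate early genes, 8.28e-12 for the stress response and 2.28e-09 for NF-kB genes. It was 0.027 for heat shock chaperones and 0.0138 for hypoxia response genes. With an estimated correlation the adjusted p was 0.0182 for immediate early genes, the 1 list of 28 whose call held, 0.308 for the stress response, 0.282 for NF-kB genes and 0.677 for both heat shock and hypoxia genes. Adjusted over the list alone, 12 NF-kB genes were higher and 1 lower, and 3 heat shock and 3 hypoxia genes were higher.

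Of 21 interferon-stimulated genes 1, Rsad2 at 0.47, was higher, and of 24 mitosis genes 2, the kinesin gene Kif11 at 0.31 and the kinase gene Ttk at 0.29, were, with 2 of each list higher when adjusted over the list alone (camera adjusted p = 0.00156 and 0.0411). Their adjusted p with an estimated correlation was 0.772 and 0.988. Of 16 NRF2 targets, genes of the oxidative stress response, 3 were lower: Pgd at -0.35, Nqo1 at -0.31 and Slc48a1 at -0.25, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.677 with an estimated correlation). The NRF2 median of -0.15 became 0.0026 when libraries were rescaled to one total, which moved the median of all genes from 0.00 to 0.12, and the list's camera adjusted p was then 0.0558. Of 10 measured purinergic signalling genes 0 passed over all genes or adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0278, and adjusted p = 0.282 with an estimated correlation). The nucleotide receptor gene P2ry2 had 0.932 ± 0.41 FPKM in treated cells and 1.43 ± 0.27 with vehicle (limma adjusted p = 0.407), and P2ry1, P2ry13 and Sost were listed at 0 in all 18 MLO-Y4 libraries. Nt5e, Pdpn, Gja1 and Tnfsf11 did not pass in treated cells or in recipients, and P2ry6, P2ry12, Entpd1, Dmp1 and Atf3 were below the filter in all MLO-Y4 comparisons.

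Lower transcripts in treated cells included mitochondrial tRNA genes. mt-Tl1, a leucine tRNA gene of the mitochondrial genome (positions 2676 to 2750), went from 184 ± 20.2 to 36.9 ± 2.31 FPKM (SD, n = 3 each), a log2 fold change of -2.28, and mt-Tm, mt-Tl2, mt-Tk and mt-Th had log2 fold changes of -1.68, -1.56, -1.20 and -1.05. Transfer RNA genes are short and were read here after poly(A) selection, so their FPKM are uncertain. Rnasek had a log2 fold change of -1.33, Ly6a of -1.08 and Snora34 of -0.96. The 13 mitochondrial DNA-encoded mRNA genes all had negative log2 fold changes with a median of -0.16, and 0 of them passed the test over all genes. Of 58 nuclear genes of oxidative phosphorylation 56 had negative log2 fold changes, and 2, Atp5d at -0.31 and Ndufb8 at -0.27, passed. Of 36 ribosomal protein genes 1, Rpl18 at -0.32, was lower. Adjusted over the list alone, 5 mitochondrial mRNA genes, 1 oxidative phosphorylation gene and 0 ribosomal protein genes were lower. By camera the adjusted p was 2.18e-05 for mitochondrial mRNA, 2.54e-06 for oxidative phosphorylation and 6.2e-06 for ribosomal protein genes. The medians of the oxidative phosphorylation and ribosomal protein lists, -0.12 each, became 0.02 and 0.03 when libraries were rescaled to one total, where the median of all genes was 0.12 and both still passed (camera adjusted p = 0.000766 and 0.0393). The mitochondrial mRNA median became 0.04 with quantile normalization (camera adjusted p = 0.994). These 3 lists had an adjusted p of 0.677 with an estimated correlation.

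Over all genes 636 of 11902 passed an adjusted p of 0.05 in limma, 442 higher and 194 lower, and 60 of them changed by at least 1 on the log2 scale. The split was 257 higher and 19 lower rescaled to one total, 218 and 17 without mt- genes, 739 and 431 with median-of-ratios scaling, 704 and 522 with quantile normalization, and 650 and 484 rescaled without satellite-like, rRNA-like and 7S genes, an alternative chosen after seeing the data. With no filter on low values 386 passed, and in a fit of only the 6 libraries 412. Vehicle replicate 2 held 28.001% of its summed FPKM in rRNA-like and 7S genes, against 0.340% to 0.537% in the other 5 libraries, and without it the split was 286 higher and 366 lower, while 395 genes passed without vehicle replicate 1, 380 without vehicle replicate 3 and 265, 282 and 300 without oligomycin A replicates 1, 2 and 3.

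**Figure D1:**
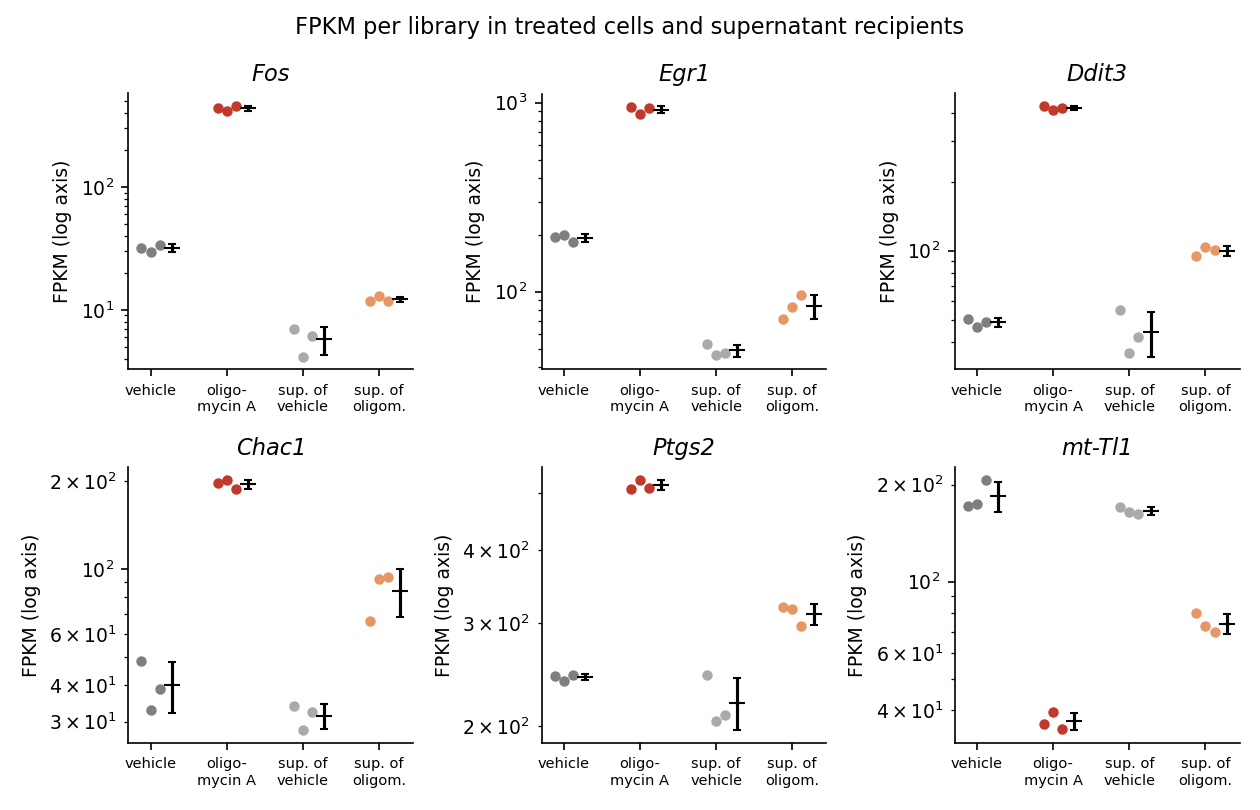
FPKM on a log axis of 6 genes in the 4 MLO-Y4 groups of the oligomycin A experiment, 1 point per library, with the mean and SD of 3 libraries as bars. Fos stood at 435 FPKM in treated cells and at 12.2 FPKM in recipients of their supernatant, against 31.9 and 5.75 FPKM in the respective controls.

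Supernatants of the treated and vehicle cells were put on other MLO-Y4 cells for 2 h, which asks whether treated cells pass on a signal. The protocol in the labels does not state that the drug was removed. Chac1 was 84.3 ± 15.6 FPKM with the supernatant of treated cells and 31.5 ± 3.10 with that of vehicle cells (SD, n = 3 each), a log2 fold change of 1.38 ± 0.15 (SE). Ddit3 was higher by 1.18, the nuclear receptor gene Nr4a1 by 1.25, Cyr61 by 1.02, Fos by 0.99, Sesn2 by 0.94, Btg2 by 0.90 and Gem by 0.87 on the log2 scale. Of 28 immediate early genes 9 were higher and 0 lower, with 18 higher when adjusted over the list alone. Of 21 stress response genes 5 were higher, including the amino acid transporter subunit gene Slc3a2 at 0.80, and 8 were higher when adjusted over the list alone. Of 19 NF-kB genes 2 were higher, Nfkbiz at 0.64 and Ptgs2 at 0.51, and 3 were higher when adjusted over the list alone. Egr1 was higher by 0.76.

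Txnip, which encodes a thioredoxin-binding protein, was 8.57 ± 1.51 FPKM in recipients of treated-cell supernatant and 20.95 ± 5.24 in their controls, a log2 fold change of -1.18. mt-Tl1 had a log2 fold change of -1.15, and Snai1, a transcriptional repressor, of -0.88. Dlx3, Ajuba, Amotl2, Hmga2 and Pdp1 ranged from -0.58 to -0.36. The 13 mitochondrial DNA-encoded mRNA genes had a median of -0.21, with 0 lower over all genes and 10 lower when adjusted over the list alone. By camera the adjusted p was 2.74e-25 for immediate early genes, 3.63e-13 for the stress response, 6.54e-13 for mitochondrial mRNA genes and 3.68e-06 for NF-kB genes. With an estimated correlation the adjusted p was 0.0666, 0.331, 0.331 and 0.385 in the same order. Of 12 p53 targets 0 were higher over all genes and 2 adjusted over the list alone, and of 15 matrix proteases and inhibitors 1 was either way, the protease gene Adamts1 at 0.68 (camera adjusted p = 0.0193 and 0.0128). Both lists had an adjusted p of 0.385 with an estimated correlation.

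Over all genes 46 passed in limma, 33 higher and 13 lower. There were 17 rescaled to one total, 14 without mt- genes, 23 with no filter on low values and 28 with a replicate block. Median-of-ratios scaling gave 81, quantile normalization 85 and rescaling without satellite-like, rRNA-like and 7S genes 90. A fit of only the 6 recipient libraries gave 7 genes, 2 higher and 5 lower, and 22 passed without vehicle supernatant replicate 2, 23 without vehicle supernatant replicate 3 and 22 without oligomycin A supernatant replicate 2. Libraries of the groups did not overlap for 13.1% of tested genes, where 10% would be expected by chance. Another split of these 6 libraries, which mixed the groups, gave 129 genes. Of the 33 higher genes, 31 were also higher in treated cells, where 1.23 would be shared by chance (Fisher's exact test, p = 8.06e-43, adjusted p = 9.67e-42 over 12 tests). Of the 13 lower genes 2 were shared (Fisher's exact test, p = 0.0183, adjusted p = 0.110). No control library was shared by these comparisons, but they came from 1 fit with the same variance estimate per gene. Genes of small spread are then called more easily in each, so these Fisher p-values can overstate the sharing. Sharing under separate fits was not tested. In the fit of only the 6 recipient libraries, 4 of the 7 genes were among the 46 in the same direction. In the shared fit 2 genes, Txnip and Zfc3h1, were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the comparisons had Pearson's r of 0.285 and Spearman's rho of 0.228.

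**Figure D2:**
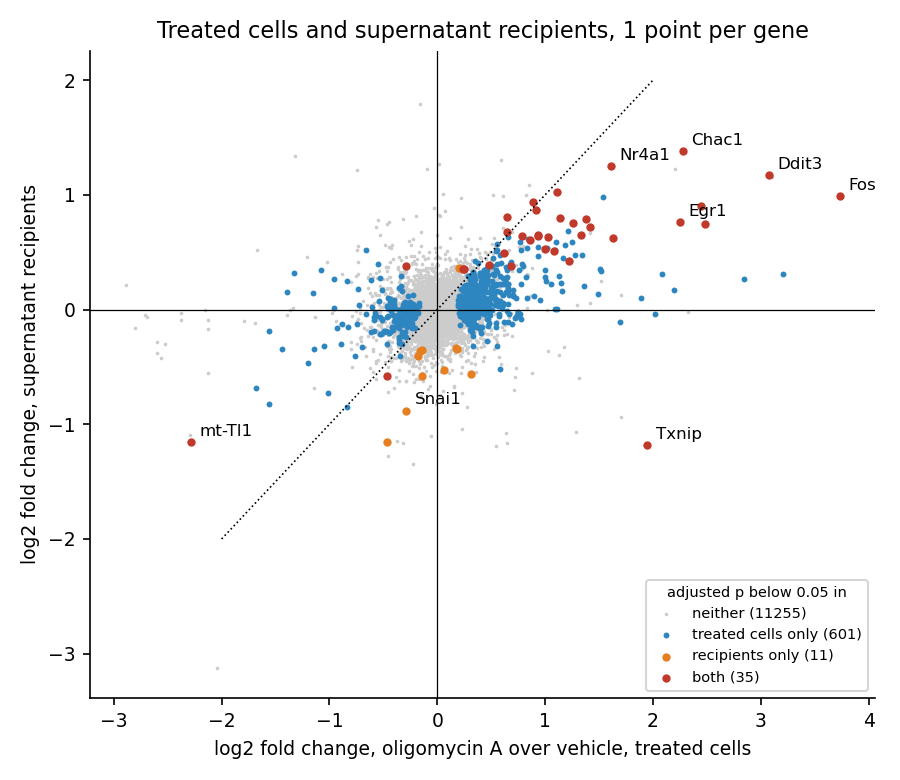
Log2 fold change of each tested gene in supernatant recipients (vertical axis) against treated cells (horizontal axis), coloured by the comparison in which its adjusted p was below 0.05; the dotted line marks equal values. Ddit3 lies at 3.08 in treated cells and 1.18 in recipients, and Txnip at 1.95 and -1.18.

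**Figure D3:**
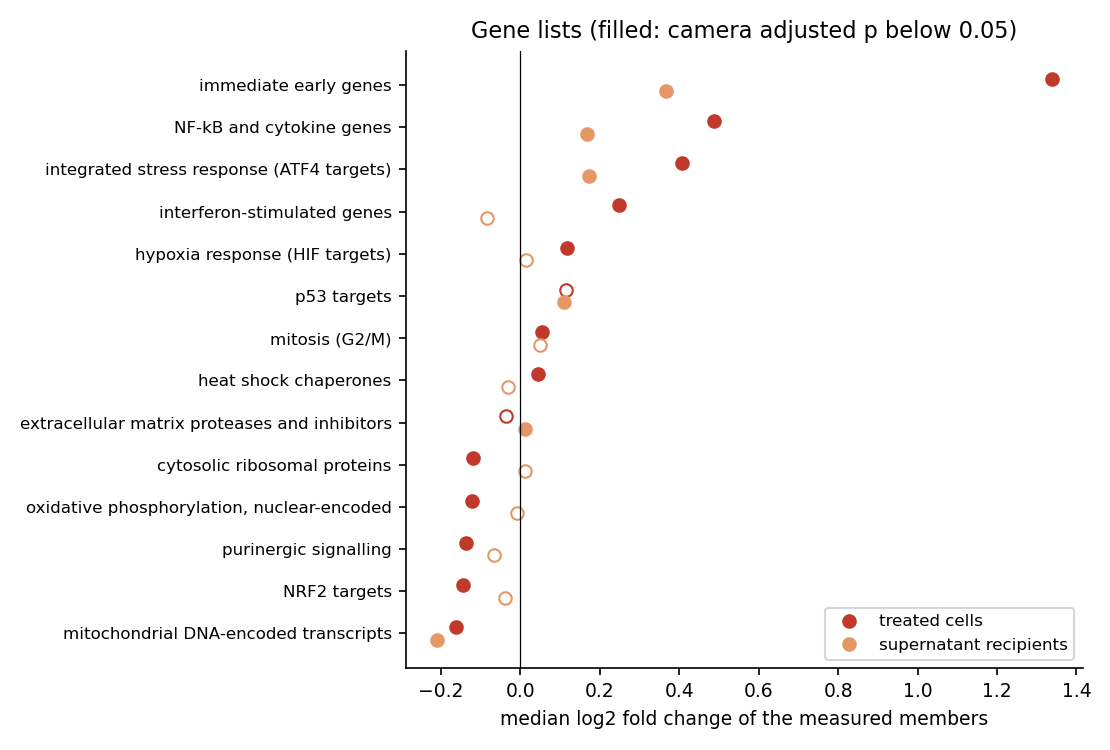
Median log2 fold change of the measured members of each gene list that passed camera with the preset correlation in either comparison, with filled points for an adjusted p below 0.05. Immediate early genes had medians of 1.34 in treated cells and 0.37 in recipients.

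The responses of recipients and treated cells were compared in one model, as recipients minus treated cells. Recipients had 2 h with supernatant and treated cells 1 h with oligomycin A, so duration is part of every such difference. Txnip had a difference in log2 fold change of -3.13 ± 0.24 (SE), with 1.95 in treated cells and -1.18 in recipients. Ier2, Fos, Zfp36, Dusp1, Ddit3 and Jun had differences from -2.89 to -1.79, and Rnasek and mt-Tl1 of 1.65 and 1.13. Of 28 immediate early genes 11 had a lower response in recipients and 0 a higher one, and 16 a lower one adjusted over the list alone (camera adjusted p = 1.96e-26, and adjusted p = 0.0583 with an estimated correlation). Of 21 stress response genes 2, Ddit3 and Ddit4, had a lower response, and 4 adjusted over the list alone (camera adjusted p = 0.000951, and adjusted p = 0.887 with an estimated correlation). In limma 53 genes passed, 10 with a higher and 43 with a lower response in recipients, and 34 and 78 when rescaled without satellite-like, rRNA-like and 7S genes. There were 31 rescaled to one total, 24 without mt- genes and 102 with median-of-ratios or quantile scaling. Without oligomycin A replicate 3, or with a replicate block, 35 genes passed, and rescaling to one total moved the median of all genes to -0.12.

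Vehicle supernatant recipients and vehicle-treated cells differed in duration, 2 h against 1 h, as well as in medium. Immediate early genes were lower in recipients, 21 of 28 with 0 higher: Fos was 5.75 ± 1.46 against 31.9 ± 2.17 FPKM, Egr1 48.9 ± 3.59 against 193 ± 8.70 and Cyr61 158 ± 20.1 against 561 ± 15.8 (SD, n = 3 each). Of 18 glycolysis genes 6 were lower and 1 higher, with the phosphofructokinase genes Pfkl at -0.58 and Pfkm at -0.51. Of 21 cholesterol synthesis genes 4 were lower, and of 17 hypoxia response genes 5, with Bnip3 at -0.54. Of 24 mitosis genes 1, Cenpf at -0.36, was lower. Of 21 stress response genes 10 were higher, with Trib3 at 1.26, as were 5 of 14 mitochondrial chaperones and proteases, with Hspa9 at 0.56. Of 18 endoplasmic reticulum chaperones 2 were higher, Herpud1 at 1.11 and Dnajb11 at 0.25. Of 9 osteocyte markers 5 were higher, with Pdpn at 0.46 and Phex at 0.39, and of 6 fibroblast markers 3, with Prrx1 at 0.46 and Dcn at 0.39. Of 21 interferon-stimulated genes 6 were higher and 1 lower. Adjusted over the list alone, 22 immediate early genes were lower and 1 higher, 9 glycolysis genes lower and 2 higher, 12 stress response genes higher and 1 lower, and 10 interferon-stimulated genes higher and 1 lower. For the other lists, 4 cholesterol synthesis and 5 hypoxia genes were lower, 0 mitosis genes were, and 6 mitochondrial chaperones, 2 endoplasmic reticulum chaperones, 5 osteocyte and 4 fibroblast markers were higher, all adjusted over the list alone.

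The camera adjusted p was 1.57e-22 for immediate early genes, 9.22e-05 for glycolysis, 0.00143 for cholesterol synthesis and 0.00159 to 0.0233 for the other 8 lists. With an estimated correlation the adjusted p was 0.0933 for immediate early genes and 0.378 to 0.710 for the other 10 lists. Of single genes, Usf3 was higher by 2.22, Dlx3 by 1.25, Foxs1 by 1.12, Snord14e by 1.10, Klf10 by 1.09 and Snai1 by 1.09, and Osgin1 had a log2 fold change of -1.93, Arc of -1.85, Klf2 of -1.55, Nptxr of -1.44 and Btg2 of -1.38. In limma 1746 genes passed, 1129 higher and 617 lower, against 1095 and 1116 with median-of-ratios scaling, 1120 and 1088 with quantile normalization, 485 and 102 rescaled to one total, 406 and 95 without mt- genes and 1134 and 986 without satellite-like, rRNA-like and 7S genes. Rescaling to one total moved the median of all genes to 0.14, and 1002 genes passed without vehicle supernatant replicate 1 and 1098 without vehicle supernatant replicate 3. Without vehicle replicate 2, the library rich in rRNA-like and 7S genes, the split was 628 higher and 731 lower.

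ADP, a nucleotide that acts on purinergic receptors, was given at 2 µM for 2 h. The lysosomal amino acid transporter gene Slc36a1 (chromosome 11, 55204350 to 55236330) went from 0.795 ± 0.036 to 2.34 ± 0.17 FPKM (SD, n = 3 each), a log2 fold change of 0.90 ± 0.06 (SE), and Fam122b, Yipf6, Pianp and Wdr81 were higher by 0.96, 0.85, 0.81 and 0.72. The predicted gene Gm28048, named here after its values were seen, was also called, at 2.78. Fos, Egr1 and Ddit3 had log2 fold changes of 0.06, 0.00 and 0.00, with adjusted p of 0.956, 1.0 and 1.0. The oxidative phosphorylation and ribosomal protein lists had medians of 0.05 each, with 0 members called, 1 oxidative phosphorylation gene lower adjusted over the list alone and 0 ribosomal ones (camera adjusted p = 0.000379 and 2.06e-06), and an adjusted p of 0.825 with an estimated correlation. The next genes by p, which did not pass, were Zmym5 at -0.66, Cdkn2d at -0.62, B3gnt2 at -0.77, AC154176.1 at 0.25 and Hmga1 at -0.39. Of 11604 genes 7 passed in limma, 6 higher and 1 lower, with 678 at an unadjusted p below 0.05 where 580 would be by chance. With quantile normalization 6 were higher and 2 lower. With no filter on low values or with a replicate block 0 passed, and with a filter at a mean of 5 FPKM 1 did. Leaving out replicate 1 or 3 of the cells without ADP gave 0 and 2 genes, and leaving out 2 µM ADP replicate 2 gave 3. Leaving out 2 µM ADP replicate 1 gave 40, that library holding 2.02% of summed FPKM in rRNA-like and 7S genes against 0.425% to 0.530% in the other 5. P2ry2 had 1.12 ± 0.10 FPKM without ADP and 1.37 ± 0.36 with it (SD, n = 3 each), with limma's adjusted p at 0.886.

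Fragments of bone from 1-month-old mice were cultured for 48 h with conditioned medium (group named medium transfer) or as controls. The labels do not say which donor's medium each group received. The satellite-like predicted genes Gm10800 and Gm10801, named after their values were seen, were called lower, at log2 fold changes of -1.97 and -1.83, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, and Cfd, complement factor D, higher, at 5.12 and 3.61. The libraries of the groups overlapped for each of these 4 genes: Lars2 was 242, 501 and 312 FPKM in the transfer libraries and 265, 0.883 and 0.812 in the controls. Dmp1, an osteocyte gene, was 165 ± 125 FPKM with transfer and 135 ± 37.9 in controls (SD, n = 3 each), and its log2 fold change of 0.03 did not pass in limma (adjusted p = 0.991). Of the other purinergic, osteocyte and stress genes fixed beforehand, 0 passed. The next genes by p, Mir466j, Traj21, Traj18, AC161114.1 and AC125488.1, did not pass. Erythroid, mitochondrial mRNA, osteoclast, V-ATPase and mitochondrial chaperone lists had medians from 0.81 to 1.33, beside a median of all genes of 0.45, with 0 members called over all genes or adjusted over the list alone. Their camera adjusted p ran from 0.000388 to 0.0491, and the adjusted p with an estimated correlation was 0.930. The mitochondrial chaperone and osteoclast medians lay at 0.22 and 0.21 without medium transfer replicate 2, the opposite direction relative to other genes. Satellite-like genes held 66.1%, 5.80% and 89.9% of the summed FPKM in the transfer libraries and 86.1%, 88.6% and 81.7% in the controls. Of 16438 genes 4 passed in limma, with 368 at an unadjusted p below 0.05 where 822 would be by chance, and 0 were higher and 2 lower rescaled to one total, with a median of all genes of 0.78, or without mt- genes. With a replicate block 0 were higher and 2 lower. A pseudocount of 0.5, no variance trend or a robust trend each gave the opposite, 2 higher and 0 lower. With a filter at a mean of 5 FPKM 1 passed. With no filter on low values 0 passed, as with median-of-ratios or quantile scaling and without medium transfer replicate 3, while 7 passed without medium transfer replicate 2, 2 without control replicate 1 and 1 without control replicate 2 or 3.

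**Figure D4:**
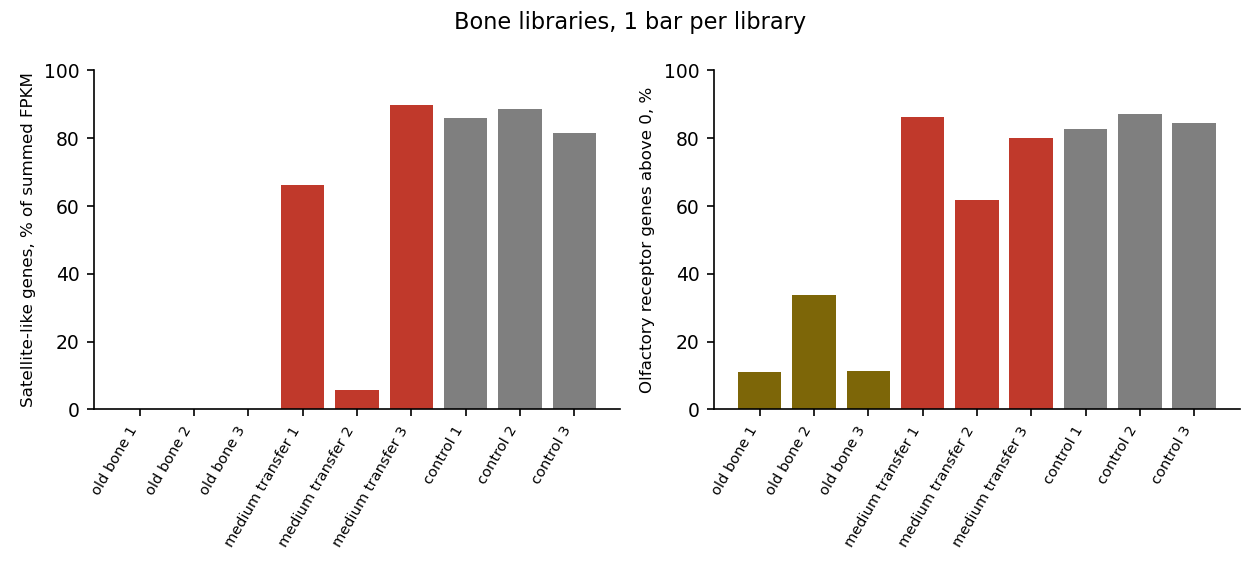
Satellite-like genes as a percent of summed FPKM (left) and the percent of olfactory receptor genes with a value above 0 (right), 1 bar per bone library. In the young bone libraries the latter was 61.7% to 87.1%, and in the old cortical bone libraries 10.9% to 33.7%.

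Cortical bone of 18-month-old mice was measured without a young counterpart in the same table, so only levels are given, and tables were normalized separately. The protocol says that nonosseous tissue with marrow was harvested and does not state that marrow was removed. Erythroid markers held 44.5% ± 0.88 of the summed FPKM (SD, n = 3), with the globin genes Hbb-bs at 103871 ± 4226 and Hba-a1 at 105305 ± 2192 FPKM. Neutrophil markers held 12.7% ± 0.45, with S100a8 at 36776 ± 1305 FPKM. Osteoblast and bone matrix genes held 0.601% ± 0.122, with the osteocalcin gene Bglap at 1732 ± 443 FPKM, and osteocyte markers 0.0148% ± 0.0131, with Dmp1 at 22.1 ± 18.9 and Sost at 3.22 ± 3.45 FPKM.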

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

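The tests on sequencing depth in young bone, on the size of the response with other scaling and on mitochondrial tRNA genes were chosen only after the result was seen.

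The response to oligomycin A differed between supernatant recipients and treated cells by the test of the difference in 53 genes. In recipients minus treated cells, the log2 differences were 1.65 for Rnasek, 1.13 for mt-Tl1, 0.92 for Mir17hg, 0.67 for Zfc3h1, 0.63 for Mir22hg and 0.43 for Nsun5. They were -3.13 for Txnip, -2.89 for Ier2, -2.74 for Fos, -2.57 for Zfp36, -2.06 for Dusp1, -1.90 for Ddit3, -1.79 for Jun, -1.49 for Egr1, -1.11 for Nfkbia, -1.01 for Ddit4, -0.58 for Ptgs2 and -0.48 for Dnaja1. List medians of the difference were -0.57 for immediate early genes, -0.16 for the integrated stress response, -0.10 for heat shock chaperones, -0.29 for NF-kB and cytokine genes, -0.32 for interferon-stimulated genes, 0.13 for oxidative phosphorylation and 0.12 for ribosomal proteins, the last 2 of which became -0.0089 and -0.027 when rescaled without mt- genes. That rescaling put the median of all genes at -0.13, and both lists still passed (camera adjusted p = 0.00164 and 0.0164). With an estimated correlation the adjusted p was 0.0583 for immediate early genes and 0.887 for the other 6 lists. Of 100 drawn splits of the 12 libraries, 3 gave at least 53 genes, the real one included, and the highest other gave 2976. These splits mix the groups' own differences into the test, such as the 1746 genes of the vehicle pair. A high count is therefore no sign of hidden structure, and the splits do not decide whether chance can be excluded.

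The smaller response in recipients was weighed against 3 explanations. It was clearest in immediate early genes, with a median difference of -0.57. Mitochondrial mRNA genes did not share it, with medians of -0.21 in recipients and -0.16 in treated cells. Duration, 2 h in recipients against 1 h in treated cells, was not tested and cannot be told apart from a weaker signal. Genes higher in recipients had a median log2 fold change of -0.0138 under 2 µM ADP (32 genes, upper 95% bootstrap limit 0.00335 over genes). By the median these genes were thus not higher at that dose. Only 7 genes passed under ADP, and 4 of 10 splits gave as many, so the libraries do not show that the ADP acted. This result therefore cannot decide on ADP in the supernatant. Genes higher in treated cells kept a median of 0.12 in recipients with median-of-ratios scaling (lower limit 0.106). That limit was drawn over genes, so it does not measure the spread between libraries. The median also does not show whether scaling makes the response smaller. With that scaling the 33 genes higher in recipients had a median difference, recipients minus treated cells, of -0.34 (upper 95% bootstrap limit -0.148), against -0.34 without it, and 26 were below 0. That scaling hardly moved the comparison: the median of all genes was -0.0049 without it and -0.0025 with it. These values argue only against a shift common to all genes as the whole cause, with genes treated as independent. Rescaling to one total, which put the median of all genes at -0.12, was not tested on these 33 genes. Of the 636 genes called in treated cells 75.2% had the same sign in recipients, between the bounds set for the test. Oligomycin A carried over with the supernatant and a signal made by the treated cells could both give the same sign. This share therefore cannot tell them apart. A released signal is the biological explanation the design names, and it stays open.

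In young bone, satellite-like transcripts dominated 5 of 6 libraries. Genomic DNA is a candidate explanation: at least 61.7% of olfactory receptor genes had a value above 0 in each young bone library, against at most 5.51% in MLO-Y4 libraries. Low depth alone is argued against by this share, since fewer fragments would detect fewer such genes, not more. Estimated fragments were at most 6.85 M in young bone against at least 14.9 M in MLO-Y4 cells. The young bone estimates are rough, since low values clustered only weakly at steps. A marrow share as large as in old cortical bone is argued against. Erythroid, neutrophil and B-cell genes held at most 4.65% of summed FPKM, against at least 56.9% in old cortical bone. Without satellite-like, rRNA-like and 7S genes they held 3.39% to 12.5%, against at least 59.6%. The old bone protocol names tissue with marrow and its values were normalized separately, so a smaller share of marrow cells stays open. No biological explanation was tested.

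Of 13 measured mitochondrial tRNA genes on the plus strand 11 had negative log2 fold changes in treated cells, the exceptions being mt-Tf and mt-Ts2, and 7 were called lower. Their median lay below that of mitochondrial mRNA genes by -0.39 (upper 95% limit -0.157) and below that of 6 minus-strand tRNA genes by -0.64 (upper limit -0.183). The strands were parted after the values were seen and the plus-strand genes had an SD of 1.12, so a general fall of mitochondrial transcripts and short gene length both stay open. Without vehicle replicate 2, the library rich in rRNA-like and 7S genes, their median was -0.61 (upper limit -0.381), against -0.56 with it, and 7 were again called lower, which argues against that library as the whole cause. The limits treat genes as independent, which neighbours on one transcript are not. In recipients the plus-strand tRNA genes had a median of -0.46, with 11 of 13 below 0 and 2 called lower. All 6 minus-strand tRNA and all 13 mRNA genes were below 0 there too, at medians of -0.15 and -0.21, with 0 called. No biological explanation was tested.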

How the results depend on the processing

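The alternative that rescales without satellite-like, rRNA-like and 7S genes and the old bone share without erythroid and neutrophil genes were chosen only after the result was seen. A further alternative, without the medium transfer libraries of lowest satellite share, was run once and dropped unread, since it picked libraries by a measured outcome tied to the called genes.

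Genes past the threshold are given for treated cells (636), recipients (46), their difference (53), the vehicle pair (1746), ADP (7) and bone medium transfer (4), in this order where all are named. With a log2 fold change of at least 1, by construction fewer, there were 60, 7, 23, 51 and 1 in the first 5. With no filter on low values there were 386 in treated cells, 23 in recipients, 0 under ADP and 0 in bone, and with a filter at a mean of 5, 1 under ADP and 1 in bone. Rescaled to the same total there were 276, 17, 31 and 587 in the first 4 and 2 in bone, and rescaled without mt- genes 235, 14, 24 and 501, and 2 in bone. With median-of-ratios scaling there were 1170, 81 and 102 in the first 3 and 0 in bone, with quantile normalization 1226, 85 and 102, and 0 in bone, and without satellite-like, rRNA-like and 7S genes 1134, 90 and 112, and 0 in bone. A fit of only the 6 libraries gave 412 in treated cells and 7 in recipients. In bone, a pseudocount of 0.5, no variance trend and a robust trend gave 2 each. By construction, rescaling to one total lowers most the library with the largest total, vehicle replicate 2 in the oligomycin A fit. Its summed FPKM was 352370, against 265160 to 282134 in the other libraries of that fit. The median of all genes was then 0.12 in treated cells and 0.01 in recipients, where that library is not compared. Apart from these constructions, the cause was not tested.

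Without single libraries of the compared groups the counts ran from 265 to 652, 22 to 59, 35 to 70, 1002 to 1359, 0 to 40 and 0 to 7. Other libraries of the shared fit were not left out, so recipients were not tested without vehicle replicate 2. Genes called higher in both treated cells and recipients (31) were 14 at an adjusted p of 0.01 and 50 with median-of-ratios or quantile scaling, and those called lower in both (2) were 1, 9 and 9. In bone, 2 lists reversed without medium transfer replicate 2: mitochondrial chaperones at a median of 0.22 (adjusted p = 0.826) and osteoclast markers at 0.21 (adjusted p = 0.85). Over all such omissions these medians ran from 0.22 to 1.36 and from 0.21 to 1.34. Old bone shares ran, without single libraries, from 44.0% to 44.9% (erythroid), 12.5% to 12.9% (neutrophil), 0.556% to 0.671% (osteoblast) and 0.00723% to 0.0186% (osteocyte). As a share without erythroid and neutrophil genes, osteoblast genes held 1.41% and osteocyte markers 0.0344%, which follows from the smaller total. Rescaling to one total leaves a share the same by construction.

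The replicate numbers did not pair the samples: same-number correlations ran from -0.228 to 0.0587, and 2, 0, 4, 0 and 0 of 6 libraries were closest to their own number in treated cells, recipients, the vehicle pair, ADP and bone. With a replicate block there were 434, 28, 35 and 1460 genes in the first 4 comparisons, 0 under ADP and 2 in bone. Of called named genes, 23 of 37 stayed past the threshold in the same direction under every alternative run in treated cells, 3 of 21 in recipients, 13 of 19 in the difference, 22 of 49 in the vehicle pair, 0 of 6 under ADP and 0 of 2 in bone, and 0 reversed. Count-based tests planned for count tables were not run, since the values are not counts. In simulated bone libraries 0% of genes changed by 1 on the log2 scale were recovered, so changes of that size were not detectable there.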

Other observations

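None of the tests in this part was chosen after its result was seen.

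Of 21 measured interferon-stimulated genes 19 had positive log2 fold changes in oligomycin A treated cells (median 0.25), with 1, Rsad2, called higher, at 0.47. In vehicle recipients against vehicle-treated cells 6 were higher, with Usp18 at 1.08, Ifi44 at 0.81 and Isg15 at 0.54, and 1 lower, Rsad2 at -0.57. With an estimated correlation the adjusted p of the list was 0.772 and 0.709 in these comparisons. Atf3, a stress response gene, was listed at 0.119 FPKM or less on average in each MLO-Y4 group while Ddit3 rose in treated cells, and at 8.22 ± 1.00 FPKM in old cortical bone (SD, n = 3).

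The number of genes past the threshold was set beside other splits of the same libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 636 genes in treated cells and the highest other 5, with 1 split as large, the real one. It gave 1746 in the vehicle pair and the highest other 3, again with 1 as large. In recipients it gave 46 and the highest other 129, with 2 as large; that split set vehicle supernatant replicate 1 with treated supernatant replicates 1 and 2. For ADP it gave 7 and the highest other 10, with 4 as large, and for bone medium transfer 4 and 12, with 5 as large.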
